A study of Candida albicans with 3 samples.

How the data were processed

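Total RNA of the 3 libraries was reverse transcribed with random hexamers, the double-stranded cDNA was sonicated, and Illumina libraries were made and sequenced, per the labels' protocols. The labels do not say that strand was kept, so reads of overlapping genes on opposite strands cannot be told apart. The aligner, the genome build, the handling of mismatches and any depletion of ribosomal RNA are not given in the sources used here, and neither is the date or batch of each library.

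Each library had an ORF table and an allele table. The ORF tables hold deposited read counts per feature, as unique and as total reads, for 12048 features with their length. The RPKM values deposited beside them are total reads scaled by ORF length and by the summed total reads, as recomputing them showed. The column of expression values in the deposited files is RPKM in library 1 and unique reads in libraries 2 and 3. The deposited normalized score computed from that column has identical sorted values in the 3 libraries, as quantile normalization gives, and the deposited transformed score is the square root of the expression values to within 0.001 in 12036, 12048 and 12048 of the 12048 features, with differences of at most 0.00126; neither score was used for a result, since the former mixes units. The allele tables hold deposited counts of unique reads for the alleles of 6398 pairs, which fixes the pairing, and no total read count in them differs from the unique count. The allele RPKM values deposited there refer to library totals of 1554925, 2039299 and 1935359 reads, which exceed the reads in the tables. The deposited p-value per pair and library agreed to within 1e-05 with a two-sided Fisher's exact test on RPKM rounded to whole numbers against the rest of each summed RPKM column, in all 1393, 1393 and 1392 pairs with reads. Rounded RPKM are not counts, so that p-value does not follow the number of reads.

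The pair tables and the ORF tables overlap but are not identical: among 1417 pairs with reads that are present in both, 1065 have the same unique reads in every library, so the ORF tables are not a second measurement for those pairs. In the allele tables, 63 second alleles occur in more than 1 pair, which places 126 pairs with a shared allele, 97 of them among the tested pairs. Of 14027 identifiers, 0 matched the reference table of gene names, so the 25 gene lists fixed by symbol were not analysed here, and coordinates are not given.

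Levels were total reads scaled with TMM factors and expressed as RPKM (edgeR 4.0.16, R 4.3.3). Correlations between libraries used log2 of CPM with a pseudocount of 1. The allelic test was edgeR's quasi-likelihood test (glmQLFit, glmQLFTest) on the 6 columns of 2 alleles by 3 libraries. The library was a block, the library size was shared by both alleles, the normalization factor was 1 and allele length entered as an offset. Pairs needed at least 10 unique reads, over both alleles, in each library. A pair was called at a Benjamini-Hochberg adjusted p under 0.05 over 1095 pairs. The common dispersion corresponded to a coefficient of variation of 10.2%, with 4.5 prior degrees of freedom. Log2 ratios per library used a pseudocount of 0.5, and their mean, SD and standard error are over 3 libraries. An allele without reads was set to a floor of 3 reads over the group, without length correction. Expression level for the 5 bins was the sum of both alleles' total reads, which 1083 of the tested pairs have.

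The test was tried on simulated counts for the 1095 pairs with the real means, of which 200 were changed. It recovered 52.2% of pairs changed 1.5-fold, 83.6% of those changed 2-fold and 100% of those changed 4-fold, and 5.42% of its calls were unchanged pairs. The simulated counts had the common dispersion in all pairs and libraries, whereas the real spread can differ between pairs and between libraries. Reads of unchanged pairs were also split between the alleles in exact proportion to their lengths, as the offset assumes. Recovery and the share of false calls therefore hold for that setting only. They do not cover pairs of unequal length whose unique reads depart from that proportion. Intervals of shares are 95% Wilson intervals; they and the floor cover counting error only, since the reads carry no molecular identifiers. Fisher's exact test, exact binomial tests and permutations used SciPy 1.17.1 and NumPy 2.4.6.

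The design, the named-gene rule and the alternatives were set before the data were examined, apart from those said to be added later. The rule named the called pairs with the largest fitted ratio and at least 2-fold in the same direction in each library; since no symbol was at hand, it was limited to 2 pairs per direction, and its parts by level, by reads and by gene list were dropped. Alternatives were another tool (DESeq2 1.42.0), other scalings, other count minimums, no length offset, no block, pairs of equal length, a fold threshold of 1.5 within the test (glmTreat), thinned reads and leaving out each library. Chosen after seeing the data were the unique reads of the ORF tables, leaving out pairs with a shared allele, leaving out pairs with under 3 reads on an allele, and thinning to 50 reads, which was added because no pair was called after the intended thinning to 10.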

Results

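RNA of Candida albicans strain SC5314 was sequenced in 3 libraries, all from yeast-form cells of the wild type. C. albicans is a diploid yeast of the human microbiota and an opportunistic pathogen, and SC5314 is the strain behind its reference genome, in which many genes are described as 2 alleles. The cells were grown at 30 °C with shaking at 200 rpm in 10 ml of YPD, a rich medium of yeast extract, peptone and glucose, from an optical density of 0.25 to an optical density of 1.0 at harvest. With 1 strain in 1 condition there were no groups of samples to compare, and the comparison the design implies is between the alleles of each gene within a library. The design text describes 1 sample assessed in triplicate, so the spread between libraries may be technical. The p-values of the allelic test for each pair measure that spread alone. Exact binomial, Fisher's exact and permutation p-values take pairs as the unit and do not measure the spread between libraries.

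The ORF tables held 12048 features with 7643796, 9505352 and 8976216 total reads in libraries 1, 2 and 3. Of these reads, 38.3%, 38.8% and 39.1% were placed uniquely. The allele tables held 6398 pairs of ORFs with uniquely placed reads alone, namely 441083, 501296 and 454122 reads in libraries 1, 2 and 3. Identifiers in the files are ORF numbers, apart from 20 features whose identifiers begin with CaalfMp. No source used here pairs any of them with gene symbols, so genes are given by ORF number and their functions are not stated.

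The highest levels per length lay mostly at short ORFs. Of the 12048 features, 9361 (77.7%) had at least 10 reads in each of the 3 libraries, and the detected number per library was 9880, 9736 and 9620. Total reads include reads shared between alleles, so this does not show each allele of a pair to be transcribed. The median level of the detected features was 14.6 RPKM after TMM scaling, with quartiles at 5.77 and 41.3. The highest was orf19.6835, 327 bases long, at 56033 ± 18476 RPKM (SD, n = 3), a feature singled out after its values were seen. Next were orf19.6834.10 at 52387 ± 16746 RPKM and orf19.2309.2 at 16122 ± 2380 RPKM (SD, n = 3). The RNA was total RNA, and neither strand nor depletion of ribosomal RNA is given. Reads of another RNA overlapping an ORF, ribosomal RNA included, can therefore not be told from those of the ORF itself. The 15 highest features lay between 10405 and 56033, with a median length of 318 bases against 1185 bases over all features. Of these 15, 12 belonged to no allele pair. Levels are per feature, and reads shared between alleles are divided between them, so the level of a paired gene is spread over both its features. The ranking and the median therefore place paired genes lower than features in no pair. Expressed as CPM, without the length, orf19.6835 stood at 18323 ± 6042 (SD, n = 3). The 10 features with the most reads took 8.94%, 10.9% and 12% of the reads of libraries 1, 2 and 3.

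Expression levels were close between libraries 2 and 3 and less so between either and library 1. Across features, the Pearson correlation of log2 CPM was 0.993 between libraries 2 and 3, 0.979 between libraries 1 and 2, and 0.977 between libraries 1 and 3; features are not independent replicates. The matching Spearman values were 0.991, 0.976 and 0.975. Among 6999 features with at least 50 reads in every library, 34 differed at least 2-fold between libraries 2 and 3, 244 between libraries 1 and 2, and 255 between libraries 1 and 3. The biological coefficient of variation estimated with edgeR was 21.8% over the 3 libraries and 9.42% over libraries 2 and 3 alone. The libraries differed by more than counting noise, with a chi-square statistic per degree of freedom of at least 7.91, so none was treated as the same library deposited again. This does not tell separate cultures from repeated preparations of the same RNA.

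The alleles of most expressed genes could not be told apart. Of the 6398 pairs, 4945 (77.3%) had no uniquely placed read on either allele in any library. Among 4590 pairs with at least 10 total reads in each library, counting both alleles in the ORF tables, 71.9% had none. Where neither allele had a unique read, the deposited total reads were divided evenly. The first allele held a median of 50.02% of the reads (quartiles 48.9% and 51.2%) in 2928 such pairs of equal length. Where unique reads existed, the remaining reads followed them, with a slope of 0.962 between the first allele's share of unique reads and its share of all other reads over 1163 pairs. The allelic comparison was therefore made on unique reads only.

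Unique reads, corrected for length, differed between the alleles in 449 of the 1095 pairs that had at least 10 unique reads in each library, or 41.0% (95% Wilson interval 38.1 to 43.9). The test was edgeR's quasi-likelihood test with the library as a block and an offset for allele length, with Benjamini-Hochberg adjusted p under 0.05. The first-listed allele was higher in 219 pairs and the second in 230, a share of 48.8% for the first (exact binomial p = 0.637, two-sided). Reads of an allele that is in more than 1 pair were counted in each, and the binomial test takes pairs as independent. Without the pairs that share an allele, a choice made after seeing the data, the first was higher in 213 and the second in 168. That is a share of 55.9% (exact binomial p = 0.0241), so the balance over all called pairs depends on the pairs that share an allele. All 449 had the same direction in each of the 3 libraries, as the test all but requires. The median difference among them was 1.24 on the log2 scale, or 2.37-fold, beside a median SD between libraries of 0.287. The count was 271 without library 2 and 241 without library 3. It was 249 with DESeq2, 299 without the library block and 247 with a threshold of 1.5-fold within the test. A total of 222 pairs were called with all libraries and with each library left out, 188 of them at least 2-fold apart.

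**Figure D1:**
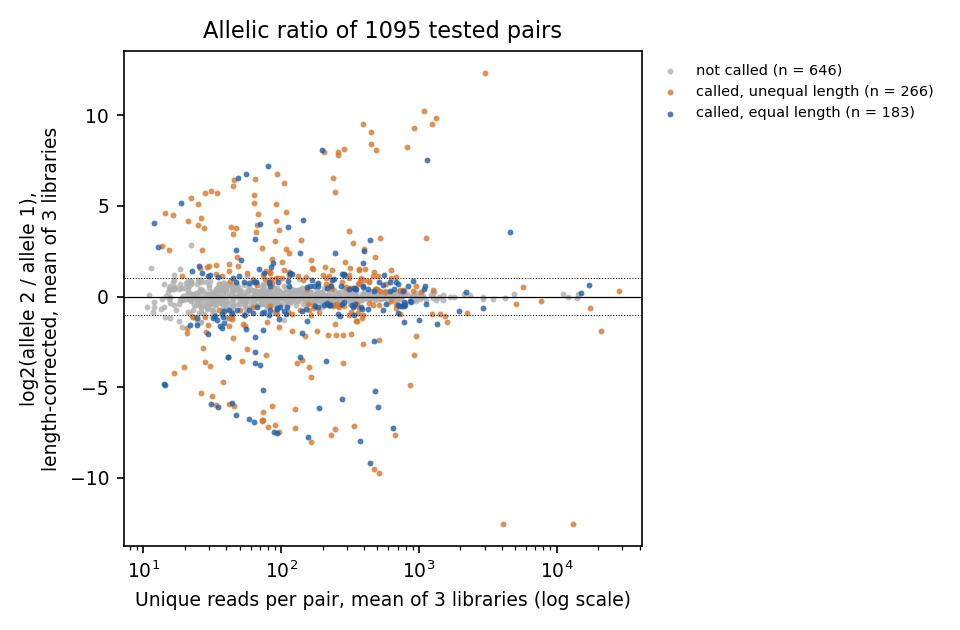
Each point is 1 of the 1095 tested allele pairs, with its mean unique reads per library (x axis, log scale) and its mean length-corrected log2 ratio of allele 2 to allele 1 over 3 libraries (y axis); dotted lines mark 2-fold differences. Of the pairs, 449 were called, 266 of unequal and 183 of equal length, and their ratios lay on both sides of 0.

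Large allelic differences were common among the called pairs. The difference was at least 2-fold in 271 pairs, with the first allele higher in 129 and the second in 142 (exact binomial p = 0.466, two-sided). In 203 of them each single library showed at least 2-fold in the same direction. Without the pairs that share an allele, the first was higher in 127 and the second in 94 of the 221 such calls (exact binomial p = 0.0311). A difference of at least 10-fold was fitted in 115 pairs, 80 of unequal and 35 of equal length. In 68 pairs 1 of the alleles had no unique read in any library, the first in 34 and the second in 34. With those alleles set to a floor of 3 reads over the group, each of the 68 pairs differed at least 14-fold in reads, without length correction. The minimum of reads per library puts every such pair at 10-fold or more in reads. With these bounds in place of the length-corrected fits, the 115 and the median of 2.37-fold were the same, which that minimum all but fixes.

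By the rule set for naming, 2 pairs stood for the largest differences in each direction. In orf19.4632/orf19.12102 the first allele had 7350, 2545 and 2250 reads and the second had 0 in every library, at least 4048-fold fewer reads against a floor of 3 reads over the group (adjusted p = 2.43e-06, edgeR). In orf19.6854/orf19.14144 the first allele had 9949, 14809 and 14383 reads and the second 2, 1 and 1, a mean log2 ratio of -12.54 ± 0.745 (SD, n = 3; standard error 0.43; adjusted p = 3.47e-08, edgeR). In orf19.506/orf19.8136 the first allele had 0 reads in every library and the second 2336, 3519 and 3145, at least 3000-fold more (adjusted p = 3.11e-06, edgeR). In orf19.3776/orf19.11257 the first allele again had 0 reads and the second 807, 1326 and 1157, at least 1097-fold more (adjusted p = 1.19e-05, edgeR). These bounds depend on single libraries: the bound of orf19.4632/orf19.12102 was 1598-fold without library 1. That of orf19.506/orf19.8136 was 1827-fold without library 2 and 1952-fold without library 3, and that of orf19.3776/orf19.11257 was 655-fold and 711-fold. The alleles of these pairs differed in length, at 519 and 441, 1344 and 1107, 1017 and 1182, and 2514 and 4455 bases in the order given. In each of them the longer allele was the higher one. Unique reads depend on how much sequence separates the alleles, which was not measured. The bounds are therefore of unique reads, and do not show the shorter allele to be expressed that much less. The last pair also shares its second allele with another pair.

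**Figure D2:**
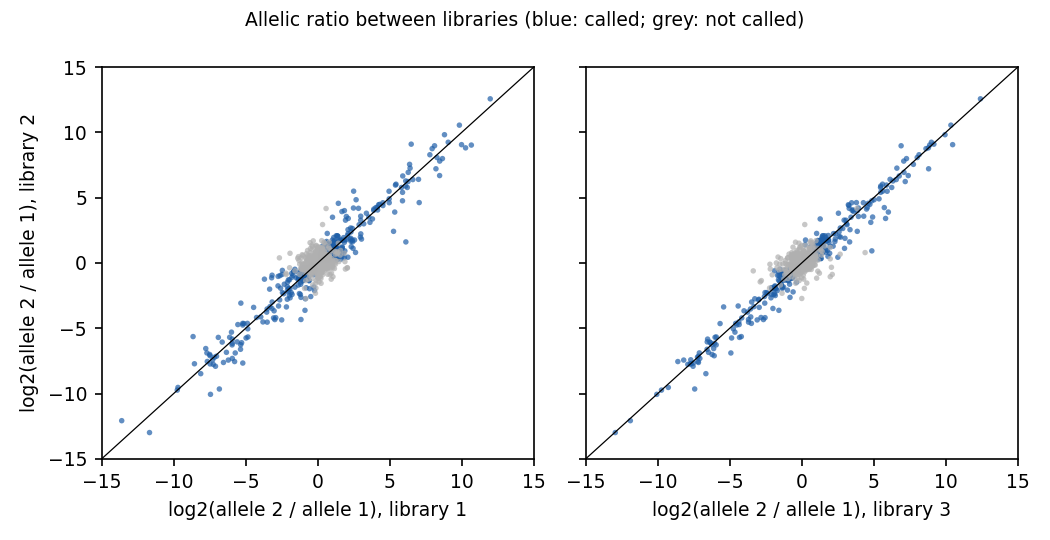
The length-corrected log2 ratio of allele 2 to allele 1 in library 2 (y axes) is plotted against that in library 1 (left) and library 3 (right) for 1095 pairs; points are pairs, the line marks equality. The Pearson correlation across pairs was 0.944 on the left and 0.962 on the right.

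Allelic ratios correlated between libraries. Across the 1095 pairs, the Pearson correlation of the log2 ratios was 0.944 between libraries 1 and 2, 0.933 between libraries 1 and 3, and 0.962 between libraries 2 and 3, and the Spearman values were 0.752, 0.735 and 0.813. The median absolute difference between libraries was 0.345, 0.376 and 0.264 on the log2 scale in the same order. In pairs of equal length the Pearson values were 0.9, 0.879 and 0.931, and the Spearman values were lower, at 0.634, 0.609 and 0.745.

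Pairs whose alleles differed in length were called more often than pairs of equal length, though not where the lengths were nearly the same. Of 500 pairs of unequal length, 266 were called (53.2%, 95% Wilson interval 48.8 to 57.5), against 183 of 595 pairs of equal length (30.8%, 27.2 to 34.6; Fisher's exact test, two-sided, p = 6.47e-14). The median difference among called pairs was 2.83-fold at unequal and 1.95-fold at equal length, and 181 and 90 of them were at least 2-fold apart. One allele had no unique reads in 55 called pairs of unequal length and in 13 of equal length. Among the 266 called pairs of unequal length, the longer allele was higher in 212, or 79.7% (74.5 to 84.1; exact binomial p = 2.64e-23), after the length offset. Both tests take pairs as independent, although some share an allele. Without the pairs sharing an allele (added later), 200 of 405 pairs of unequal length and 181 of 593 of equal length were called. The longer allele was then higher in 151 of the called pairs of unequal length, or 75.5% (exact binomial p = 2.74e-13). Unique reads depend on how much sequence separates the alleles, which the offset does not measure. At equal length, 80 pairs were called with DESeq2, 100 without the block, 79 with the fold threshold, 95 without library 2 and 80 without library 3.

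**Figure D3:**
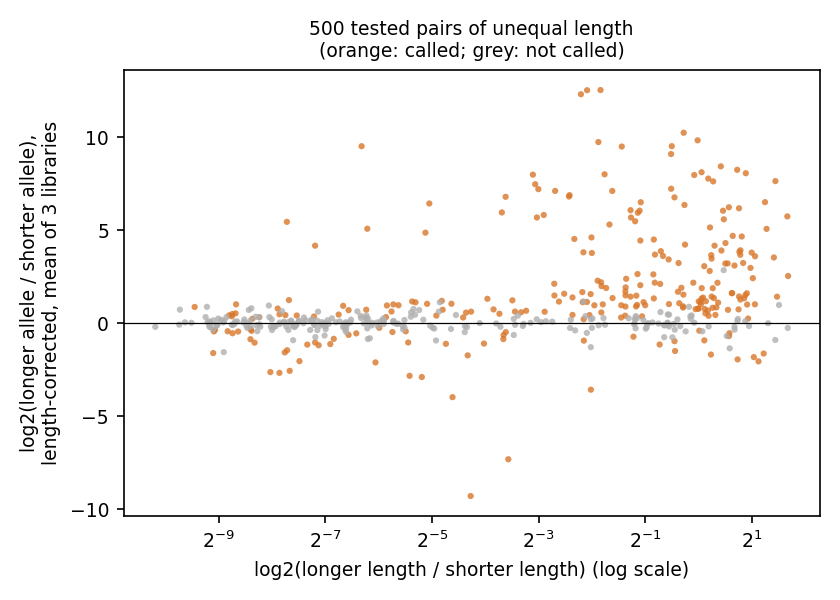
For the 500 tested pairs of unequal length, the length-corrected log2 ratio of the longer to the shorter allele (y axis, mean of 3 libraries) is plotted against the log2 ratio of their lengths (x axis, log scale); orange points were called. The longer allele was higher in 212 of the 266 called pairs, and the excess lies mostly at large length ratios.

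The share of called pairs was higher at higher expression, together with the number of reads. Over 5 bins of expression level with equal numbers of pairs, 1083 in all, it was 34.1% (95% Wilson interval 28.1 to 40.6), 34.3%, 38.2%, 45.4% and 53.0% (46.4 to 59.5) from the lowest to the highest. The median unique reads per pair and library in the same bins were 34, 80.5, 94, 250 and 553. Without library 2 the lowest and highest bins had 15.7% and 36.9%, and without library 3 they had 11.5% and 32.7%. With pairs of at least 50 reads thinned to 50 reads per library, an analysis added after thinning to 10 reads had left no calls, the shares were 26.2%, 28.9%, 27.0%, 30.6% and 29.6%, and the interval of the lowest bin (15.3 to 41.1) held that of the highest (23.7 to 36.2). Only 42 pairs of the lowest bin had 50 reads, against 203 of the highest, and 35.7% and 53.2% of them were called before thinning. A difference in called share between levels was not detectable at that depth with this number of pairs. Differences of at least 2-fold were called in 28.1% of the pairs of the lowest bin and in 24.0% of those of the highest.

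**Figure D4:**
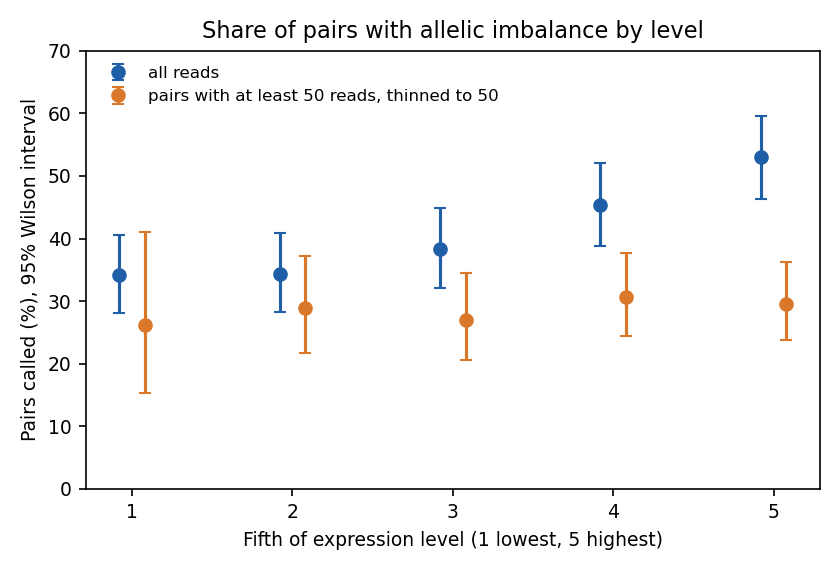
Points give the percentage of tested pairs called for allelic imbalance in each of 5 bins of expression level (x axis), with 95% Wilson intervals, for all reads and after thinning pairs with at least 50 reads per library to 50. The share went from 34.1% to 53.0% with all reads and stayed between 26.2% and 30.6% after thinning. The thinned points rest on 42, 128, 152, 186 and 203 pairs from the lowest to the highest bin.

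The authors' deposited tables give a p-value per pair and library, which was under 0.05 in 410, 351 and 345 pairs of the 6398 in libraries 1, 2 and 3. By the authors' deposited tables, 258 pairs had such a p in all 3 libraries, 257 of them with the same allele higher by reads per length. Of the 258 pairs in the authors' deposited tables, 255 were among those tested here and 253 were called here, while 196 pairs called here did not reach a p under 0.05 in every library there. The deposited p is an unadjusted Fisher's exact p on rounded RPKM for each library. A call here rests on 1 adjusted p from the counts of all 3 libraries. With thresholds so unlike, the 253 and the 196 measure neither agreement nor gain.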

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

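The tests on library 1 below were set before their results were seen, after the correlations at full depth had been. No test for an outlying sample was run on the 3 libraries, and with 1 group no contrast could differ between groups. Reads were found in features outside the allelic comparison. The 1274 features with ORF numbers that belong to no pair held 2467162, 3186940 and 3051584 total reads in libraries 1, 2 and 3, or 32.3%, 33.5% and 34.0% of all reads, of which 93.4%, 93.1% and 93.1% were placed uniquely. The 20 features whose identifiers begin with CaalfMp held 455, 38 and 54 reads, or 59.5, 4 and 6.02 CPM, above the 3 reads that a count of 0 allows.

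As a description, with no such test, library 1 stood apart from libraries 2 and 3 in features with at least 2-fold differences, in the coefficient of variation and in the CaalfMp features. The correlation of libraries 2 and 3 exceeded the better of the others by 0.0146. Depth is argued against: after thinning all libraries to 7643796 reads on average the gap was 0.0143. Whether reads concentrated in a few features contribute cannot be told. The gap was 0.0159 without the 100 features with the most reads. The correlation counts every feature equally, so leaving out these few could change it little, and nothing is concluded from that value. A batch or culture difference may remain, which the labels do not name, and no biological explanation was tested.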

How the results depend on the processing

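The 4 named pairs kept their direction and call in every alternative in which they were tested, and the longer allele stayed higher in 73.5% to 88.1% of called pairs of unequal length. The 449 calls became 249 with DESeq2, 299 without the library block, 247 with the fold threshold of 1.5 in the test, and 182 when only the 595 pairs of equal length were tested; leaving out 1 library gave 241 to 540. The 183 calls at equal length became 80 with DESeq2, 100 without the block and 79 with the fold threshold, and 80 to 248 without 1 library. The 271 calls of at least 2-fold became 161 with at least 50 reads and 88 at equal length, by construction of the smaller sets, and 202 to 293 without 1 library. The direction was near balance except that, with pairs sharing an allele left out (added later), the first allele was higher in 55.9% (exact binomial p = 0.0241), and in 127 of 221 calls of at least 2-fold. The shared allele is listed second. Calls with the second allele higher went from 230 to 168, and with the first higher from 219 to 213. At unequal length they went from 266 to 200, with the longer allele higher in 212 and then 151, and at equal length from 183 to 181. Why the first allele was higher in more of the remaining calls was not tested. With the unique reads of the ORF tables (added later), 422 pairs were called; of 395 earlier calls testable there 377 were called, 13 in the opposite direction. Most pairs have the same counts in both tables, so this is a partial check. Other scalings gave 457 and 462 calls and moved the median log2 ratio to -0.02 and -0.03. The correlations of library 1 with libraries 2 and 3 were 0.9699 and 0.9683 over features with at least 10 reads, and the highest feature stood at 18323 without length scaling. The called share by level, 34.1% in the lowest and 53.0% in the highest bin, was 11.5% to 38.7% and 32.7% to 65.9% without 1 library. It was 26.2% and 29.6% after thinning to 50 reads (added later). After thinning to 10 reads it was 0% in both: edgeR gave 169 pairs an unadjusted p under 0.05 and a smallest adjusted p of 0.163, although 100 pairs had all reads on 1 allele, so that setting decides nothing. DESeq2 was not run on thinned reads. Alternatives for gene lists were not run. The allelic test covers 17.1% of the pairs: of 6398, 4945 had no unique read, 3300 of them although expressed, and of the 1453 with unique reads 1095 reached the count minimum.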

Other observations

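The tests on allele length were chosen after the result was seen; the others in this part were set before their results were seen. Genes whose alleles can be told apart lay beside each other in the order of ORF numbers. Among 4590 expressed pairs, 28.1% had uniquely placed reads. Following a pair with such reads by at most 3 numbers, with the same difference between the allele numbers, the next expressed pair had them in 55.4% of cases, against 14.6% after a pair without. Over 4169 such neighbours, 77.7% shared their state, against a median of 59.6% in 10000 random placements (permutation p = 0.0001, the smallest they can give). Random placements among pairs with the same difference between allele numbers gave a median of 63.7% (permutation p = 0.0005, the smallest that 2000 can give). A hypothesis is that sequence differences between the alleles are unevenly spread over the genome; ORF numbers may follow chromosomal order only in part, and no coordinates were used.

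For the allelic ratios themselves no such order was detected. Among 228 neighbours of equal length, the Spearman correlation of the log2 ratio was 0.049 (approximate 95% interval -0.0853 to 0.182; permutation p = 0.463). The bound set for arguing against ratios shared along a haplotype was met: an absolute correlation under 0.1 with a permutation p not under 0.05. The interval, considered afterwards, crosses 0.1, so a weak sharing cannot be told apart from none with this number of neighbours. Alleles listed first need not lie on the same haplotype either, which could hide a sharing.

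The longer allele was higher in 79.7% of called pairs of unequal length. The share was 48.9% (95% Wilson interval 35.0 to 63.0) in the third of pairs whose lengths differed by up to 1.01-fold, 80.6% up to 1.36-fold, and 90.2% (83.7 to 94.3) up to 9.25-fold. A candidate explanation is sequence present in 1 allele only, where each read is unique, so that unique reads go beyond proportion to length. The excess of the longer allele rose with the length ratio (Spearman rho 0.428 over 500 pairs, permutation p = 0.0001, the smallest they can give), as this requires. A lower level of truncated alleles would give the same order and stays open, untested.

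In 35 called pairs of equal length, 1 allele was at least 10-fold above the other, the first in 24 and the second in 11, with a median of 80.3 reads per pair and library. Of the 32 pairs present in the ORF tables, 29 (90.6%, 75.8 to 96.8) kept a 10-fold difference in the same direction, which met the bound set for arguing against the mapping reference as the cause. That bound was wrong, because 27 of the 32 have identical counts in both tables; of the 5 counted differently 2 kept the difference and 1 had the other allele higher, so the mapping reference cannot be told apart from allelic expression. Loss of 1 haplotype over a run of ORFs cannot be told apart either: 1 of 17 next tested pairs (5.9%, upper bound 27.0%) was at least 10-fold apart, against 10.5% of all tested pairs. An error in the reference sequence or a further gene copy might give the same values and was not tested.

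Exchanging the allele names within a library gives 4 distinct assignments, too few for a share under 0.05. The real one, 1 of the 4, gave 449 called pairs with edgeR and 537 at an unadjusted p under 0.05. The highest of the others gave 0 called pairs and 3 at an unadjusted p under 0.05. DESeq2 was not run on them. An exchange in 1 library sets real differences against each other and turns them into spread between libraries. Few calls would follow in any case, so the 0 is no null for the 449 and nothing is concluded from it.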
